A study of Drosophila melanogaster with 4 samples.

How the data were processed

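Iso-Seq libraries were made from polyadenylated RNA of testes of control males (2 samples) and of males with kmg knocked down through the bamGAL4 driver (2 samples), with 150 pairs of testes per sample and sequencing runs of 24 hours, per the labels' protocols. Parents laid eggs over 3 days at 25 °C, and the progeny then developed at 29 °C. The authors deposited 1 annotation (GTF) that merges all 4 libraries. Per the deposited file's own name, transcript models were merged with TAMA, corrected, filtered, filtered again through tappAS and given predicted CDS; the settings, the aligner and the versions are not given in the sources used here. The genome builds BDGP6 and dm6 are named in the submitters' processing notes, and both are Release 6 of the genome. The deposited values are positions of transcripts, exons and CDS parts with the reading frame; they hold no read number, no sample, no condition and no gene name. The depth per sample is therefore unknown, and replicate spread could not be measured.

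The comparison of control and knockdown that the design implies could not be made from this file, since 0 lines name a sample or condition. Merging, correction and filtering by the authors also set which isoforms can be seen. The isoform numbers within the 9100 listed loci run to a sum of 114135, of which 40180 (35.2%) are listed. Locus numbers run to 14207, and isoforms of loci that are not listed do not enter that share.

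Gene names came from a table of RefSeq gene spans of the Release 6 plus ISO1 MT assembly, which gives neither strand nor exons. It had 16695 genes on the chromosome arms used, which were 2L, 2R, 3L, 3R, X and Y. All 40180 isoforms lay on these arms, so the catalogue holds no isoform of chromosome 4 to examine. The strand of a gene was taken from isoforms with an end within 200 bp of the matching end of the gene, where at least 80% of them agreed, and 294 genes stayed ambiguous. An isoform received the name of the gene on its strand, extended by 200 bp, that held at least 50% of its span and overlapped best. In this way 34653 isoforms (86.2%) of 9000 genes were named, and 36.7% of these isoforms ended within 10 bp of the gene's 3' end. A gene whose isoforms match neither end is left without a name, so that a gene without an outer start is named only through its 3' end or a start within 200 bp. These naming rules were chosen after the file was seen.

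A start counted as outer when it lay within 100 bp of the 5' end of the gene span. Because annotated exons were not used here, the planned definitions changed in 4 ways. Annotated starts became the outer end of the gene span. A first exon in an annotated intron became a first exon wholly inside an intron of an isoform of the same gene that starts over 100 bp farther 5', without overlap with exons of such isoforms, joined to an acceptor they share. The annotated CDS became the longest CDS among isoforms from the outer end. Matching on annotated intron length became matching on gene length in 10 classes. The planned test of core promoter motifs needs genome sequence and was not run.

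Shares were given with exact binomial (Clopper-Pearson) intervals of 95%. Groups of genes were compared with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment, with 0.05 as the threshold, and with 10000 random lists matched on gene length. For the CDS comparison 1 isoform per gene and class was drawn at random with a fixed seed. Intervals and tests run over isoforms or genes, which are not replicates. Random placements (100 per test) were used in the closing observations. Alternatives covered distances of 50, 200 and 500 bp, spliced isoforms alone, starts of any gene, shared donors, any acceptor, isoforms with a CDS, overlap by exon length, other naming rules, genes with at least 2 isoforms and genes with a single RefSeq transcript.

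The groups of genes were fixed before the data were examined: Kmg and remodeller subunits, meiotic arrest genes, spermatid differentiation, Y-linked fertility, germline stem cells and spermatogonia, cyst cells and other testis somatic cells, neuronal (with the glial repo and the muscle receptor gene GluRIIA), muscle, gut with fat body and epidermis, and photoreceptor genes. The rule for named genes was fixed then too. It takes kmg, examples from each group in the order of isoform number, the 10 genes with the most isoforms from an internal first exon, the 10 genes without an outer start whose nearest spliced start lies farthest from the annotated one, and the 5 genes with the most isoforms. The ranking of genes without an outer start was applied to genes with internal starts alone, a limit that the fixed rule did not hold. Members of a group that had no outer start or an internal first exon, and genes with a single RefSeq transcript, were named in addition after their values were seen, as were positions in so and simj.

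The steps were tested on simulated data with 5000 genes, in which every gene had an isoform that matched an annotated end. The strand was recovered for 98.6% of genes, outer starts for 97.6%, and 193 of 200 internal first exons (96.5%). Of all 7437 simulated isoforms, 0 were wrongly called internal first exons. The simulation held no other spliced isoforms that start in an intron, so that value says little about false calls. Fisher's test was tried on simulated groups of 12 genes at an unadjusted p under 0.05. Groups with a share of 50% against 12% passed in 90.2% of draws, and groups with no difference in 4.2%. The groups tested here held 3 to 22 spliced genes, most of them under 12, and were judged after adjustment. The simulated power therefore does not carry over to them. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.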

Results

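Long-read RNA sequencing (PacBio Iso-Seq, in which a polyadenylated transcript is read as a full-length cDNA) was carried out on testes of Drosophila melanogaster. Testes carrying the bamGAL4 driver, which is active in spermatogonia, served as the control in 2 samples, and testes that also carried an RNAi construct against kmg, directed by that driver, made up the 2 knockdown samples. Kmg (Kumgang) is a zinc-finger protein of spermatocytes, and the series asks whether a complex of this cell type keeps cryptic promoters silent during differentiation. Each sample came from 150 pairs of testes of males 0 to 2 days old, after a shift of the progeny from 25 to 29 °C. The data analysed here are 1 merged catalogue of transcript structures from all 4 samples, with 40180 isoforms at 9100 loci. Its lines carry no read number, so the depth of each sample is unknown, and 0 lines name a sample or a condition.

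The kmg gene itself was represented by 5 isoforms (2L, 13160527 to 13163153, plus strand, Release 6 coordinates). Of these, 2 started at 13160476 and 13160509, next to the annotated 5' end, and 3 started together at 13160715, inside an exon of a longer isoform and 188 bp from the annotated end. In all 5 the coding sequence (CDS) began at 13160806. It ended at 13163106 in 4 isoforms, and at 13162383 in the unspliced isoform, whose CDS of 1578 bp is shorter than the 2244 bp of the longest. Whether kmg transcripts fell in the knockdown, and which isoforms belonged to the control, the knockdown or both, could not be read from a merged catalogue. No comparison of the 2 conditions was made for any gene, and every value below describes control and knockdown testes pooled.

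Among 9000 genes that received a name, 8498 were protein-coding, 354 were long non-coding RNA genes and 126 were antisense RNA genes. The transcription factor gene lola had the most isoforms (46), followed by salto (45) and by Syp, gish and nrv2 (39 each). Syp encodes an RNA-binding protein, gish a casein kinase and nrv2 a subunit of the sodium pump. For salto, 32 of the 45 isoforms started at the annotated 5' end of the gene, and for Syp 18 of 39, against 5 of 46 for lola and 1 of 39 for gish. A locus had a median of 3 isoforms, 2822 loci (31.0%) had 1, and 86.2% of all isoforms were spliced. The X chromosome contributed a smaller share of its protein-coding genes (1210 of 2197, 55.1%, 95% exact binomial interval 53.0 to 57.2) than chromosomes 2 and 3 (7282 of 11645, 62.5%; odds ratio 0.735, two-sided Fisher's exact test across genes, p = 6.67e-11). On the Y chromosome 6 of 24 protein-coding genes were named. Genes are not replicates, and intervals and p-values across genes or isoforms describe this catalogue and cover counting error only.

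A cryptic promoter would place a transcript's 5' end away from the annotated start, so isoform starts were set against the outer 5' end of the annotated gene. Of 34653 named isoforms, 16429 (47.4%) began within 100 bp of that end, and 18224 (52.6%, 95% exact binomial interval 52.1 to 53.1) began elsewhere. Starts inside an exon of a longer isoform of the same gene, as in kmg, were the most frequent of these, with 7685 isoforms (22.2%) of 3201 genes. Upstream starts made up 3783 isoforms (10.9%) of 2059 genes. A further 2322 isoforms (6.70%) of 898 genes had a separate exon of their own in an intron of a longer isoform. It was joined to an acceptor that this or another longer isoform of the gene also used. These are called internal first exons, and longer here means a start over 100 bp farther 5'. A start away from the outer end can still be an annotated promoter, since only gene spans were used here. The share fell to 43.2% in genes with a single RefSeq transcript and to 36.2% with a distance of 500 bp.

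**Figure D1:**
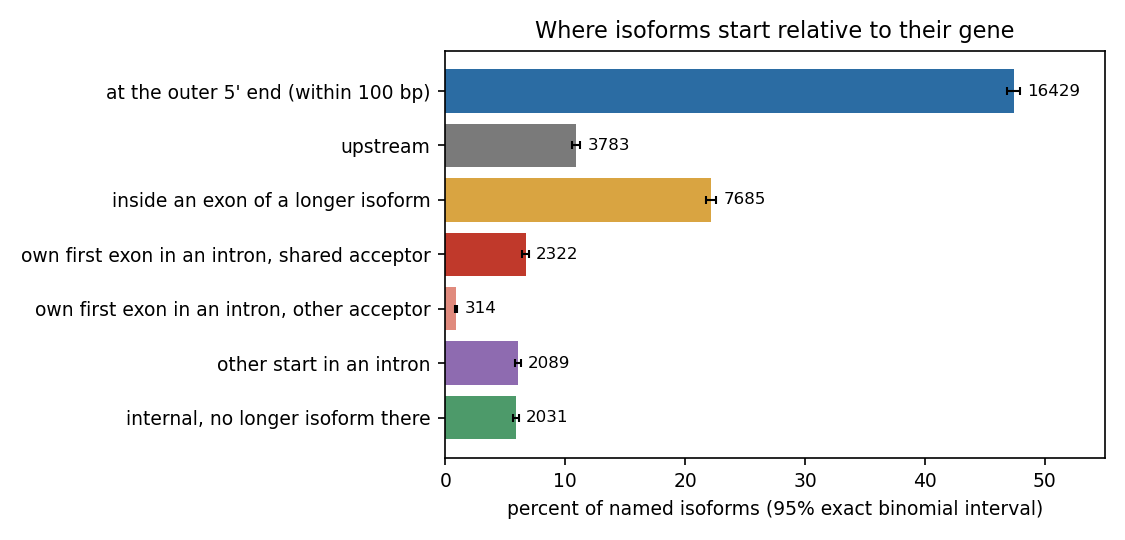
Share of the 34653 named isoforms in each class of start position (horizontal axis, percent; whiskers, 95% exact binomial intervals; number of isoforms beside each bar). Starts at the outer annotated 5' end (47.4%) are followed by starts inside an exon of a longer isoform (22.2%).

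Internal first exons were most numerous in sm, a gene for an RNA-binding protein (2R, 19517864 to 19631508), where 30 of 36 isoforms began at one. They used 2 splice donors, and the farther start lay 84437 bp inside the gene. It was followed by CLIP-190, which encodes a microtubule-binding protein (24 of 28 isoforms), the centrosomin gene cnn (23 of 33), the RNA-binding protein gene bru1 (19 of 25) and the Nrf2-related cnc (17 of 28). The genes gish (16 of 39), Syp (15 of 39), Ogdh, a metabolic enzyme gene (15 of 23), SPoCk, a calcium pump gene (13 of 20), and Eb1, a microtubule-binding protein gene (12 of 22), completed the 10 genes with the most such isoforms. In bru1 the farthest internal first exon lay 134382 bp from the annotated 5' end. In all, 898 of 7740 genes with a spliced isoform had an internal first exon (11.6%, 95% exact binomial interval 10.9 to 12.3), with 1511 distinct donors and a median exon length of 184 bp. With at least 2 isoforms required to share the donor, 334 genes were left.

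Each of these 10 genes has several RefSeq transcripts, between 6 (Eb1) and 21 (sm), so that their internal starts can be known promoters. Among 3191 spliced genes with a single RefSeq transcript, 77 (2.41%, interval 1.91 to 3.01) had an internal first exon, against 821 of 4549 genes (18.0%) with several (odds ratio 8.91, two-sided Fisher's exact test, p = 4.29e-118). Such an exon can be called only where a longer isoform of the gene is listed. Genes with a single RefSeq transcript made up 4212 of the 9000 named genes but held 10610 of the 34653 named isoforms. Isoform number and gene length were not matched here and can contribute to the gap. The 77 were led by CG46312 on the X chromosome, with 12 of 15 isoforms, then by ken, which encodes a zinc-finger repressor, and CG42245 (5 isoforms each). The homeobox gene so (sine oculis) and ERp60, a protein disulfide isomerase gene, had 4 each. In so (2R, 7419350 to 7434872), 3 of 17 isoforms started at the annotated 5' end and 7 upstream of it, the farthest at 7416037. Its internal first exons began at 7421031, 7421035 and 7433552. The isoforms from 7421031 and 7421035 kept the CDS of 1251 bp, while the isoforms from 7433552 held 417 and 366 bp of CDS with the same stop. This restriction to genes with a single RefSeq transcript was added after the data were seen.

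**Figure D2:**
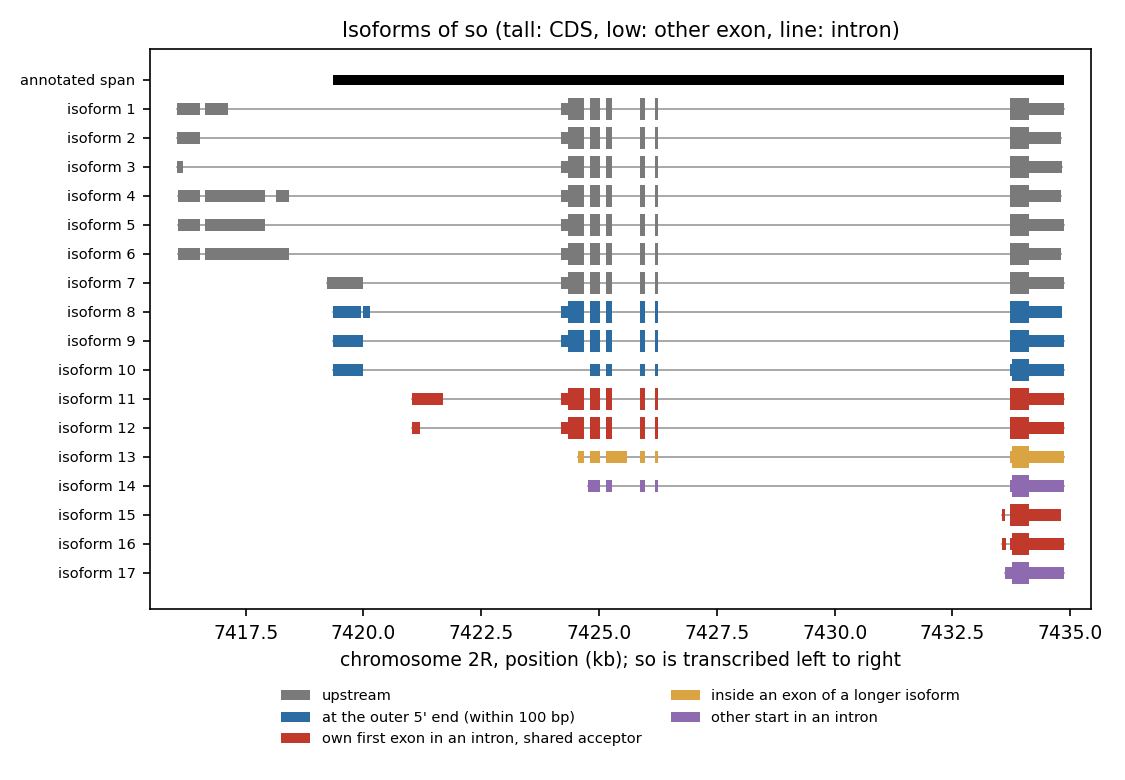
The 17 isoforms of so on chromosome 2R (horizontal axis, position in kb), coloured by class of start, with CDS as tall boxes, other exons as low boxes and introns as lines. Isoforms in red start at internal first exons at 7421031, 7421035 and 7433552; the black bar is the annotated gene span.

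In 1726 of the 9000 named genes (19.2%, 95% exact binomial interval 18.4 to 20.01), no isoform started at the outer annotated 5' end. Of these, 1093 had internal starts alone and 633 had upstream starts. Among the genes with internal starts alone, the nearest spliced start lay farthest from the annotated end in lovit, a gene for a neuronal transporter. Its single isoform of 5 exons began 385147 bp inside a gene of 434041 bp on 3L and had no CDS in the catalogue. Ptp61F, a tyrosine phosphatase gene, came next with a nearest spliced start at 122954 bp, although an unspliced isoform began at 1461 bp. The other 8 were CG1677 (119604 bp), CG43867 (105950 bp), CG41520 (78173 bp), the exchange factor gene RhoGEF64C (73214 bp), prage (64504 bp), the POU-domain gene pdm3 (60183 bp), CG4374 (58685 bp) and CG32373 (58346 bp). Of the 10 genes, lovit alone has a single RefSeq transcript. After lovit, the genes with a single RefSeq transcript and the farthest starts were beat-Vc (31408 bp), fipi (28518 bp) and Tmtc1 (22415 bp). The share of genes without an outer start depended on the distance allowed: it was 25.3% at 50 bp and 10.4% at 500 bp.

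The repressor's own group, Kmg and subunits of chromatin remodelling complexes, had 7 of 8 members named. Mi-2, the remodelling ATPase known as a partner of Kmg, had 2 isoforms (3L, 19882051 to 19910215, minus strand). The first began at 19910203, at the outer end, with a CDS of 5949 bp that stopped at 19882449. The second had an internal first exon at 19888814 and a CDS of 4926 bp. That CDS ended at 19883510, next to the isoform's own 3' end at 19883509, short of the stop of the first. The difference in CDS length thus does not come from the start alone. For simj, a subunit of the same complex, all 6 isoforms started at least 20443 bp inside the gene, at 10685182 or farther 3' on 3L, and all 6 shared the CDS stop at 10689110. Mi-2 has 4 RefSeq transcripts and simj 5, so that their internal starts can be known promoters. MTA1-like had 8 isoforms, 3 of them at the annotated end, and mip40 had 5, 3 of them at that end. With 1 of 7 genes showing an internal first exon (14.3%), the group was not detectably different from other genes (11.6%; odds ratio 1.27, two-sided Fisher's exact test, adjusted p = 1). Adjusted p-values in this and the following comparisons of gene groups are Benjamini-Hochberg values over the 10 groups fixed before the data were examined.

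**Figure D3:**
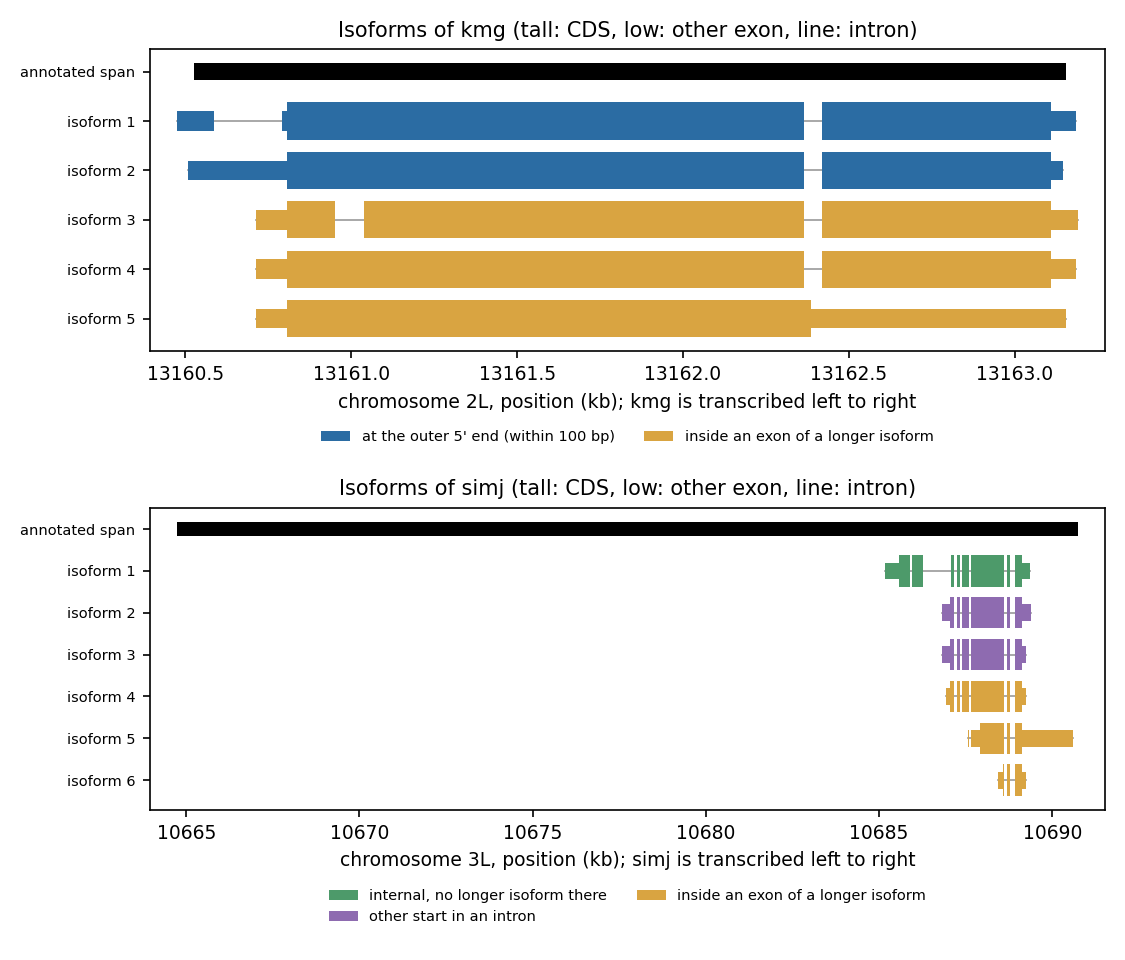
Isoforms of kmg on 2L and of simj on 3L (horizontal axes, position in kb), coloured by class of start, with CDS as tall boxes, other exons as low boxes and introns as lines. In kmg, 2 isoforms start at the annotated 5' end and 3 start 188 bp inside it; in simj the nearest start lies 20443 bp inside the annotated span, drawn in black.

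Among the germline groups, all 23 genes of spermatid differentiation were named, including bol (19 isoforms, 13 of which started inside exons), twe, the Cdc25 phosphatase gene of meiosis (7), and Mst77F, a sperm chromatin gene (7). In 22 of the 23 an isoform started at the annotated 5' end; Mst87F was the exception, with 1 isoform, and 2 of 22 spliced genes, bol and Mst35Bb, had an internal first exon (9.09%, Fisher's exact test, adjusted p = 1). The Kmg and remodeller group shares mip40 with the meiotic arrest genes, which encode regulators of transcription in the testis. Of the meiotic arrest genes 11 of 13 were named, and all 11 had an isoform at the annotated 5' end. There topi had 7 isoforms, mia 6, and achi 5, and achi was the 1 gene of 10 spliced ones with an internal first exon (Fisher's exact test, adjusted p = 1). Of the group of germline stem cells and spermatogonia, 9 of 15 were named. In it chinmo (19 isoforms) and AGO3 (7) had internal first exons, in 4 and 5 isoforms (2 of 9 genes, 22.2%, Fisher's exact test, adjusted p = 0.937), bgcn had 4 isoforms and bam 3, and stg, with 2 isoforms, had no start within 100 bp of the annotated 5' end (nearest 477 bp). Of the Y-linked fertility genes 5 of 11 were named, kl-5, ORY, Pp1-Y1, Pp1-Y2 and ARY; Pp1-Y1 had no start at the annotated 5' end (nearest 177 bp), and 0 of the 3 spliced ones had an internal first exon (Fisher's exact test, adjusted p = 1).

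Of the genes of cyst cells and other somatic testis cells, 9 of 13 were named, and zfh1, eya, so and Sox100B, all genes for transcription regulators, made 4 of 8 spliced genes with an internal first exon (against 11.6% of other genes; odds ratio 7.65, two-sided Fisher's exact test, p = 0.00858, adjusted p = 0.0858). The single isoform of Egfr, the epidermal growth factor receptor gene, started upstream, 10837 bp from the annotated 5' end. The difference in internal first exons did not pass the correction, and random lists of the same gene lengths had a mean of 38.4% (permutation p = 0.738). Of the neuronal list, which also holds the glial gene repo and the muscle glutamate receptor gene GluRIIA, 6 of 23 genes were named, while 12 more were overlapped by isoforms without receiving the name. Gad1 (8 isoforms), repo (3) and GluRIIA (1) had no start at the annotated 5' end, Ddc had 3 isoforms there, and 0 of 5 spliced genes had an internal first exon (Fisher's exact test, adjusted p = 1). In the muscle group, with 12 of 16 genes named, Mhc (7 isoforms), Strn-Mlck (5) and wupA (2) had no start there, and Zasp52 (11) and Mlc1 (4) had internal first exons (2 of 12 genes, 16.7%, Fisher's exact test, adjusted p = 1). Of the genes of gut, fat body and epidermis 9 of 17 were named. Desat1, a desaturase gene, had 20 isoforms, 10 of them from internal first exons, srp had 4 of 7 from such exons (2 of 9 genes, 22.2%, Fisher's exact test, adjusted p = 0.937), and byn, GATAe and Lsp2 had no start at the annotated 5' end. Of the photoreceptor genes 6 of 15 were named, and trp (5 isoforms), inaD (1) and Rh4 (1) had no start at that end, while 0 of 6 had an internal first exon (Fisher's exact test, adjusted p = 1). The share of genes without an outer start passed the test against other genes in 0 of the 10 groups (two-sided Fisher's exact tests, lowest adjusted p = 0.347), a comparison added after the data were seen.

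**Figure D4:**
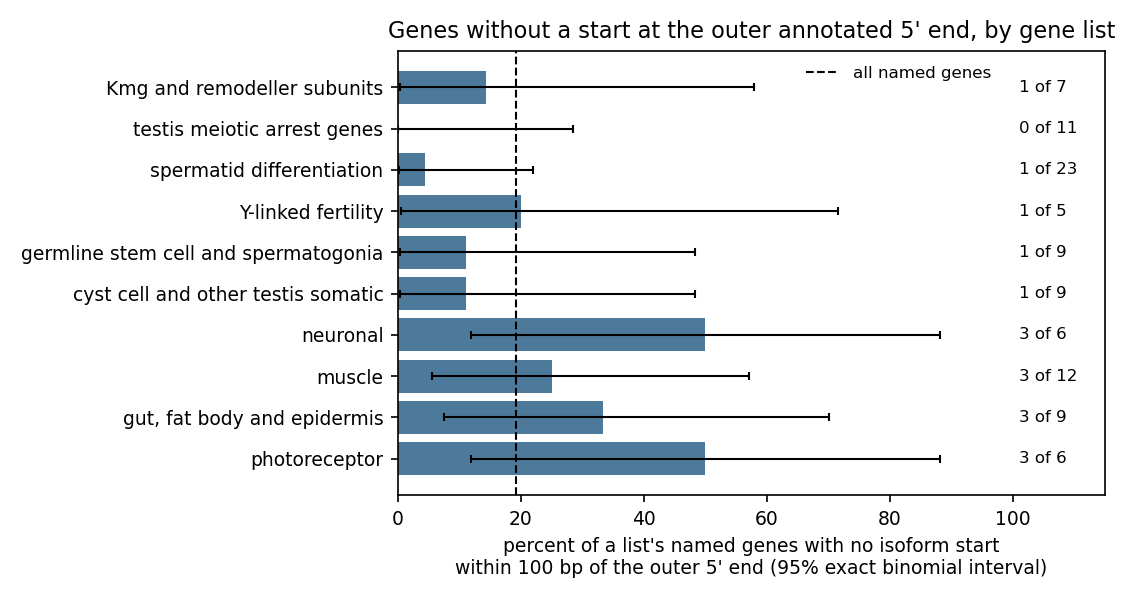
Percent of the named genes of each of the 10 groups without an isoform start within 100 bp of the outer annotated 5' end (horizontal axis; whiskers, 95% exact binomial intervals; numbers of genes at the right; dashed line, 19.2% of all named genes). The shares lie between 0 of 11 meiotic arrest genes and 3 of 6 genes of the neuronal and of the photoreceptor list, with wide intervals.

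The coding sequences of isoforms with different starts were compared with 1 isoform per gene and class, against the longest CDS among isoforms from the gene's outer 5' end. Genes without such a reference CDS were left out, so the share with a CDS was measured in genes with a coding isoform. The share with a CDS was not detectably different between isoforms from internal first exons, as in Mi-2 and so, and other isoforms from the outer end (97.5% of 726 and 97.6% of 3637; Fisher's exact test, adjusted p = 0.895). The CDS start was shared by 41.9% of isoforms from internal first exons (95% exact binomial interval 38.3 to 45.7) and by 83.1% from the outer end (81.8 to 84.3; odds ratio 0.147, Fisher's exact test, adjusted p = 2.21e-105). This share is partly set by position, since 390 of 708 isoforms from internal first exons (55.1%) began 3' of the reference CDS start, as in Mi-2 and at 7433552 in so, and cannot contain it. Among the 318 that began 5' of it, 93.4% (interval 90.1 to 95.9) shared it, against 84.1% (82.9 to 85.3) from the outer end, the opposite direction (odds ratio 2.67, Fisher's exact test, p = 1.77e-06). The CDS stop was shared by 86.3% against 79.7% (odds ratio 1.60, Fisher's exact test, adjusted p = 5.23e-05), a difference of 6.59 percentage points that was 14.7 points in genes with a single RefSeq transcript (Fisher's exact test, p = 0.00693). Of isoforms starting inside exons, the class of 3 kmg isoforms, 66.8% began past the reference CDS start; 30.4% shared that start and 88.3% the stop, with a median CDS length of 77.4% of the reference, against 96.2% for internal first exons. Adjusted values come from two-sided tests with Benjamini-Hochberg adjustment over 6 comparisons, and the restriction by position was added after the data were seen. The outer-end class leaves out the reference isoform of each gene, which shares its own CDS start and stop. It thus holds isoforms whose CDS is not longer than the reference, from genes with several outer isoforms. Isoforms from internal first exons or inside exons went through no such choice. The tests are unpaired, and the classes do not hold the same set of genes. Which genes and isoforms enter each class can therefore contribute to these differences, and no comparison within genes was made. All isoforms of genes with a reference CDS were also counted, 1902 from internal first exons and 8776 others from the outer end. The share with a CDS was then higher for internal first exons by 0.943 percentage points (Fisher's exact test, p = 0.0153). That is the opposite direction to the value with 1 isoform per gene.

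Genes on the X chromosome had internal first exons less often than genes on chromosomes 2 and 3, with CG46312 and prage among the X-linked examples. The counts were 95 of 1080 spliced genes (8.80%, 95% exact binomial interval 7.17 to 10.6) and 803 of 6655 (12.1%, 11.3 to 12.9; odds ratio 0.703, two-sided Fisher's exact test, p = 0.00149). Among genes with at least 2 isoforms the shares were 12.2% and 15.6% (odds ratio 0.752, Fisher's exact test, p = 0.0135).

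A part of the catalogue lay outside annotated genes or ran across several. Isoforms that overlapped only genes of the other strand numbered 1164 (2.90%, 95% exact binomial interval 2.74 to 3.07), and 58.2% of them had a CDS. Another 449 isoforms (1.12%, 1.02 to 1.23) overlapped no gene on either strand, with a median length of 1092 bp and a CDS in 12.7%. Of these 41.6% were spliced, and among spliced isoforms of the catalogue the share was 0.540%. Isoforms across exons of several genes of the same strand numbered 1408 (3.50%, 3.33 to 3.69), with a median length of 2646.5 bp, and 413 of them received no gene name. Their share was 2.29% when overlap of at least 50% of the exon length was required. A further 2452 isoforms (6.10%) lay in genes whose strand was not settled, or met no exon of a named gene.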

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

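The alternatives on genes with a single RefSeq transcript, on genes with at least 2 isoforms, on the naming rules, on the position of the CDS start, on gene groups without an outer start and on the pooled gene groups were chosen after the data were seen. The share of isoforms starting away from the outer 5' end (52.6%) became 59.1% at 50 bp, 46.1% at 200 bp and 36.2% at 500 bp, which follows from the wider window. It was 51.5% with the outer ends of any gene, 43.2% in genes with a single RefSeq transcript, 51.2% with a naming distance of 50 bp, 49.4% with 90% of the isoform inside the gene and 54.7% with genes named from isoforms of 1 strand alone. The share of genes without an outer start (19.2%) became 25.3%, 15.03% and 10.4% at 50, 200 and 500 bp, 20.2% with spliced isoforms, 17.0% in genes with a single RefSeq transcript, and 15.9%, 16.8% and 24.2% under those same 3 naming rules. Genes with an internal first exon (898) fell to 334 with a donor shared by 2 isoforms by construction, and to 77 with a single RefSeq transcript, where fewer genes enter but the share also fell to 2.41%; the other settings stayed within 1.5 times. The share of isoforms across several genes was 2.29% by exon length and 3.82% in spliced isoforms, of those on the other strand alone 2.36% and 2.12%, and of those outside genes 0.540% in spliced isoforms. The difference in isoforms with a CDS turned to 0.943 percentage points with all isoforms of genes with a reference CDS, where genes with many isoforms weigh more. The difference in shared CDS starts, negative in the main comparison, turned to 9.29 points among isoforms that start 5' of the reference CDS start and to 7.64 among those with an exon over it, which leave out starts past it. Apart from the causes named, the cause was not tested. In 70 tests of the 10 gene groups under alternatives, 0 had an adjusted p under 0.05 (lowest 0.0984, cyst group). The lower share of internal first exons on the X chromosome held among genes with a long intron and genes with at least 2 isoforms, and the share of genes with any start over 100 bp from the outer end was lower there too. No paired analysis was possible because all 4 libraries share 1 merged annotation without values per replicate; for the same reason the settings without each replicate and the clusters of starts per condition were not run. The motif alternatives were not run, since they need genome sequence. Depth is unknown, so a gene or isoform missing here is not shown to be absent.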

Other observations

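The tests of the contrast between somatic and germline groups in this part, and the alternatives to it, were chosen after the data were seen; the tests of truncation and of neighbouring genes were written before their results, except for the bound of hidden isoforms in the last paragraph, which was added afterwards.

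Many genes differed in the length of their 3' untranslated region (UTR) within the catalogue. Among 5382 genes with at least 2 isoforms of the same stop and the same last exon start, 1958 (36.4%, 95% exact binomial interval 35.1 to 37.7) had 3' UTR lengths at least 200 bp apart. The widest range was in Orct2, an organic cation transporter gene on 3R, from 143 to 3659 bp in 3 isoforms. It was followed by Fas1, a cell adhesion gene (32 to 2580 bp, 10 isoforms), the chaperone gene Droj2 (127 to 2659 bp, 9 isoforms) and the G protein subunit gene Gbeta13F on the X chromosome (35 to 2420 bp, 20 isoforms). In CycG, a cyclin gene, 16 isoforms ranged from 454 to 2630 bp, and in bun 9 isoforms ranged from 116 to 2181 bp. The longest 3' UTR of Orct2 is longer than its whole annotated span (24273029 to 24275728), so that isoform ran past the annotated gene. How far transcripts that run past the gene's end account for the wide ranges was not tested.

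A CDS stop more than 50 bp before the last exon junction, the arrangement that can mark a transcript for nonsense-mediated decay, was found in 2024 of 29036 spliced isoforms with a CDS (6.97%, interval 6.68 to 7.27). With 1 isoform per gene, it was found in 4.41% of 862 isoforms from internal first exons and in 4.77% of 5808 from the outer 5' end (odds ratio 0.921, two-sided Fisher's exact test, p = 0.731), a difference that was not detectable here. Over all isoforms, where genes with many isoforms weigh more, the shares were 5.70% (4.78 to 6.74) and 7.66% (7.22 to 8.13). For AGO3, all 7 isoforms were listed without a CDS. The dynein gene kl-5 on the Y chromosome had 1 isoform, from 137524 to 83952 on the minus strand, which started at the annotated 5' end and stopped short of the annotated 3' end at 22250.

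A contrast between lists of somatic tissues and of germline genes was noticed in the shares without a start at the annotated 5' end. Of the named genes in the neuronal, muscle, photoreceptor and gut, fat body and epidermis lists, 12 of 32 (37.5%) had no such start: Gad1, repo, GluRIIA, Mhc, wupA, Strn-Mlck, byn, GATAe, Lsp2, trp, inaD and Rh4. Of the spermatid, meiotic arrest and germline stem cell genes, Mst87F and stg had none (2 of 43, 4.65%; difference 32.8 percentage points). The pools were formed after the shares had been seen and left out the cyst list (1 of 9, 11.1%) and the Y-linked list (1 of 5), which go against the contrast, and the Kmg and remodeller list (1 of 7, simj), which is neither somatic nor germline by its choice. With the cyst and Y-linked lists included the counts were 13 of 41 and 3 of 48 (25.5 points). A test of the pools restates the observation that prompted them, so no p-value is given, and no single list passed its own test. Some starts lay just past 100 bp, such as that of wupA at 102 bp; with 500 bp the counts were 7 of 32 and 0 of 43 (21.9 points).

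Chance in the choice of lists, gene length, annotated transcripts and isoform number all remain open for that contrast. In 10000 pairs of random lists a difference as large arose in 0.130% of pairs matched on gene length, 0.0900% on annotated transcripts, 0.0600% on isoform number and 0.49995% on all 3 together, but these pairs carry no choice of lists. When the pooling of 4 against 3 lists with the highest difference was taken from 10 matched random lists, 12.2% to 24.1% of draws gave a difference as large, so the values decide nothing. Low read numbers of somatic genes, and the need to match a gene end before a gene is named, also stay open. A biological hypothesis, from the question of the series, is that some of these genes may be transcribed from other starts when kmg is knocked down; it was not tested, because control and knockdown are merged.

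Starts inside exons, as in kmg, may come from transcripts that lost their 5' end. If truncation were spread evenly and nearby starts were not merged, such starts should coincide no more than random positions do. Of the 7685 isoforms, 23.6% began within 10 bp of an isoform of the gene with other introns, against 2.45% on average (1.91 to 3.12) in 100 random placements. This outcome had been set beforehand to count against evenly spread truncation. The authors' merging of nearby starts could also raise the share, however the starts arose, and the random placements received no merging. The test therefore leaves truncation open, evenly spread or at preferred sites, and no biological explanation was tested.

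Upstream starts, as in so, could stem from transcription running in from a neighbouring gene. Of 3783 upstream starts, 16.9% lay inside another named gene of the same strand, within the range of 16.2 to 19.5% of 100 draws at the same distances from random genes. The test leaves the explanation open, although its outcome had been set to count against it, because the naming rule can hide such isoforms: 258 isoforms across several genes took the name of the more 5' gene and 413 had no name, and with these added the share would be 29.4%. This addition can only raise the share, and the random draws received none, so 29.4% is an upper bound for named genes and not a test. Starts inside neighbouring genes that were not named could not be counted.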
